A study of Drosophila melanogaster with 2 samples.

How the data were processed

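RNA was measured from the brains of Drosophila melanogaster larvae that carried repo-GAL4 and UAS-UPRT, so that uracil phosphoribosyltransferase (UPRT) was expressed under a glial driver. UPRT converts 4-thiouracil into a nucleotide that enters newly made RNA, and the thiol then allows that RNA to be tagged and separated. Per the labels, larvae of 64 to 88 h were fed 4-thiouracil for 8 h, brain RNA was extracted with Trizol, and thio-labelled (tagged) RNA was separated from untagged RNA. Per the labels' protocols, 50 ng of tagged RNA was labelled with Cy5 and 200 ng of untagged RNA with Cy3 for a custom Agilent array with both dyes. The series holds 2 arrays, described as biological replicates, which form 1 group. Both arrays used the same dye for the same fraction, so a dye effect of a probe is part of its ratio.

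The authors deposited a table with 1 log ratio per transcript ID and array, treated here as a log2 ratio. The scanner program, the normalization, the filter behind empty cells and the way spots were combined are not given in the sources used here. The logarithm's base is not given either. The lowest value would correspond to an 8318-fold ratio in base 10, a 15.1-fold ratio in base 2 and a 50.4-fold ratio in natural logs. Base 2 was taken, and natural logs stay possible. The direction of the ratio is likely tagged over untagged, because the titles name tagged first and the labels call tagged RNA the test and untagged RNA the reference. The deposited values had a mean of -0.00085 on the first array and -0.0014 on the second, so a shift common to all transcripts would not be visible. Both value columns belong to samples of the series. No signal intensities were used here, so the brightness behind a ratio is unknown, and the number of arrays limits the precision.

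The table lists FlyBase transcript IDs without gene names. Names were taken only from a RefSeq gene table (assembly Release 6 plus ISO1 MT), whose synonyms contain some of these IDs. Of 15456 IDs, 13 were listed for 1 gene, 22 for 2 genes and 15421 for none. Of the 13, 7 matched an exact synonym and 6 matched within a longer synonym. IDs listed for 2 genes were not named. Because no source names the genome build of the array, no coordinates were printed and gene lengths were not used. The 26 gene lists fixed before the data were examined, among them glia, neurons and neuroblasts, had between 0 and 1 measured named member. The planned list test needed 5 and was not run. LanA, in the extracellular matrix list, was the one measured member.

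Transcripts measured on both arrays were tested with limma 3.58.1 in R 4.3.3. An intercept was fitted to the 2 log2 ratios of each transcript and tested against 0 with eBayes, two-sided, with Benjamini-Hochberg adjustment at 0.05. Each transcript had 1 residual degree of freedom, and the prior added 1.92. The values had not been filtered or centred again. No gene had more than 1 named transcript, so averaging over a gene's probes changed nothing. Separately, transcripts at least 2-fold apart on both arrays were counted. A sign permutation of 2 arrays cannot give a p below 0.5, so no exact test of a single transcript was informative.

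The fit was tested on simulated data with 8140 transcripts, rounded to 2 decimals like the deposited values. With most transcripts changed, the true ratios were the observed means, apart from 1987 set to 0 and 200 of known size. Noise used a prior of 4.44 degrees of freedom, fitted after rounding error was added back, against 1.92 in the real fit. The fit called 82.1% of the transcripts simulated at a log2 ratio of 0.5, 97.0% at 1 and all 66 at 2. It made 4445 calls, against 6160 in the real table, and 0.74% of them were unchanged transcripts. The unchanged share was set in advance and no error common to both arrays was simulated, so 0.74% is not the error rate of the real calls. With only 200 transcripts changed, it called none of those at 0.5, 1.5% at 1 and 75.8% at 2. The reach of the test therefore depends on how many transcripts differ.

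A rule for the genes named in the text was written before the data were examined. It takes the 12 highest and 12 lowest genes past the test, fixed marker genes where measured, and extremes of each list. With 11 named genes measured on both arrays, all 11 are reported, also mio and HDAC3, which the rule did not choose. Wdr59, CG31178 and 2 unnamed IDs at each end were likewise added outside the rule. Alternatives changed the centring, the scaling, the variance model, the threshold, the fold limit and the transcripts tested. Rounding and the base of the logarithm were added as alternatives after the data were examined. Python 3.11.15 with numpy 2.4.6 was used for bootstrap intervals.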

Results

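The study asked whether thio-labelled RNA recovered from intact larval brains differs from the untagged RNA of the same brains when UPRT is expressed in glia, which are few, dispersed and hard to dissect. Tagged and untagged RNA were hybridised together on each of 2 arrays, giving 1 ratio per transcript and array. The table listed 15456 transcript IDs. A ratio was given for 8336 IDs on the first array and for 8401 on the second, with 46.1% and 45.6% of cells empty. Both arrays measured 8140 IDs, against 4531 if the arrays had been filled independently, which replicates with the same probes would exceed in any case. A further 457 IDs had a ratio on 1 array, and 6859 had none. In what follows a positive log2 ratio means a higher level in tagged RNA, the likely direction of the deposited ratios, and base 2 is assumed. Were the ratios deposited the other way, higher and lower would change places in every statement, ranks included.

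Tagged and untagged RNA differed over a large part of the transcripts measured, in both directions. Of 8140 transcripts, 3400 were higher and 2760 lower in tagged RNA, and 1980 did not pass (limma, Benjamini-Hochberg adjusted p under 0.05, 2 arrays). These calls rest on limma's sharing of variance across transcripts: an ordinary one-sample t statistic gave 0 calls after the same adjustment, with 2763 transcripts at an unadjusted p under 0.05. The transcripts that were lower reached further from 0 than those that were higher. Mean log2 ratios ran from -3.90 to 2.25, with 5th and 95th percentiles of -1.57 and 1.23. At least 2-fold on both arrays, 623 transcripts were higher in tagged RNA and 864 were lower, against 98.1 and 122 if the arrays were independent. Replicates that share probes and dyes exceed such counts in any case, so the excess shows repeatability and not its source. At least 3-fold on both arrays, 46 were higher and 334 were lower. The balance was the other way at 1.5-fold, with 1929 higher and 1702 lower, and at 2-fold with the values read as natural logs, with 1525 higher and 1416 lower. The median transcript stood at 0.11 on the first array and 0.10 on the second. Centring each array on its median gave 427 transcripts at least 2-fold higher and 1034 lower, and moved the higher share of the calls from 55.2% to 49.3%. At 1.5-fold, centring gave 1543 higher and 1968 lower, so the balance at that limit turned with it. Because both arrays carried the tagged fraction in Cy5, these counts include any constant dye effect of a probe. The series also holds no array without UPRT or without 4-thiouracil. A ratio therefore cannot be assigned to expression in glia, to RNA made during feeding in other cells or to the purification. Nor can these be told apart from how much of a transcript was newly made, since the label enters newly made RNA.

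The ratios of the 2 arrays were close to each other. Across transcripts, which are not independent replicates, Pearson's r was 0.962 and Spearman's rho 0.962, and 93.4% of transcripts had the same sign on both arrays. The difference between arrays had an SD of 0.25 log2 units, and 95.6% of transcripts lay within 0.5 units. It exceeded 1 unit for 48 transcripts, and the largest difference was 1.97. The smallest mean ratio that passed the limma test was 0.22 in size.

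**Figure D1:**
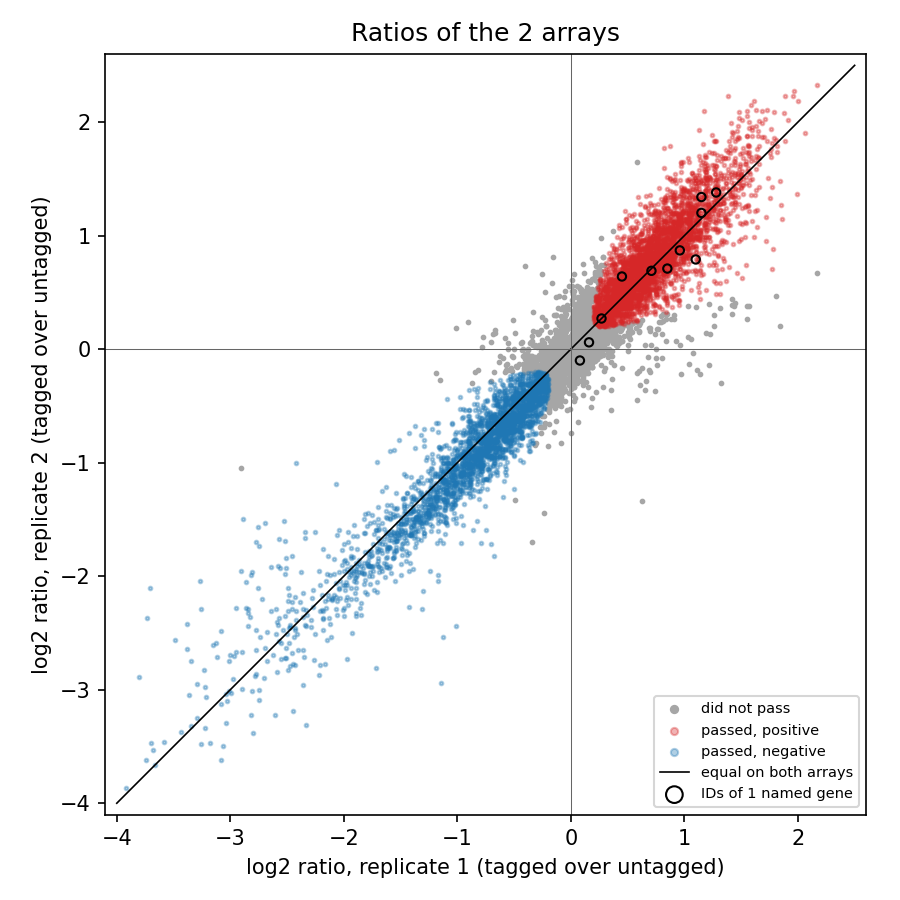
Each point is 1 of the 8140 transcripts measured on both arrays, with the log2 ratio of tagged over untagged RNA on replicate 1 (x axis) and replicate 2 (y axis). Red and blue points passed the limma test above and below 0, grey points did not, open circles are the 11 named transcripts, and the line marks equal ratios; points follow the line (r = 0.962), with a longer tail below 0 than above it.

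Of the 11 measured transcripts with 1 gene name, 9 were higher in tagged RNA, 0 were lower and 2 did not pass. This set is 0.135% of the transcripts measured on both arrays, and it was defined by what the gene table listed, so it does not represent the array. The forked end gene fend (FBtr0071349), which encodes a transmembrane protein involved in neuromuscular targeting, was the highest, at 1.33 ± 0.07 (SD, n = 2), a 2.51-fold ratio with a limma adjusted p of 0.0050. Dyrk3 (FBtr0100406), a kinase of the DYRK family, was 2.37-fold higher in tagged RNA, with a log2 ratio of 1.25 ± 0.13 (SD, n = 2) and a limma adjusted p of 0.0050.

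The 1 measured member of the extracellular matrix list was LanA (FBtr0077014), a laminin alpha chain of basement membranes. It was 2.26-fold higher in tagged RNA, with log2 ratios of 1.15 and 1.20 on the arrays, a mean of 1.18 ± 0.04 (SD, n = 2) and a limma adjusted p of 0.0050. The transcript of alpha-Spec (FBtr0072789), which encodes the alpha-spectrin of the membrane skeleton, was 1.93-fold higher. Its arrays stood further apart, at 1.10 and 0.79, with a limma adjusted p of 0.0085. After centring, which subtracted the array medians of 0.11 and 0.10, the means were 1.07 for LanA and 0.84 for alpha-Spec. A shift of that size could not have changed either direction.

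Further transcripts with smaller ratios also passed. SuUR (FBtr0076203), a chromatin protein that limits replication of heterochromatin, was at 0.92 ± 0.06, and the phosphate transporter gene NaPi-III (FBtr0076213) was at 0.78 ± 0.10 (SD, n = 2 each). CG16974 (FBtr0080489) was at 0.70 ± 0.01, and Uba1 (FBtr0088499), the ubiquitin-activating enzyme, was at 0.55 ± 0.13 (SD, n = 2 each). The limma adjusted p values of these transcripts ran from 0.0052 for SuUR to 0.014 for Uba1.

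The gene table also named transcripts of Wdr24, mio and Wdr59, which encode subunits of GATOR2, a complex that regulates TORC1 signalling. Wdr24 (FBtr0085543) had a log2 ratio of 0.27 on each array and passed with a limma adjusted p of 0.031, but after centring its mean was 0.17 with a limma adjusted p of 0.087. The transcript of mio (FBtr0077835) had a mean of 0.11 and a limma adjusted p of 0.22. Wdr59 (FBtr0080196) had a ratio on the second array alone, at 0.59, and was not tested. HDAC3 (FBtr0078767), a histone deacetylase, had values of 0.08 and -0.10 and a limma adjusted p of 0.91. CG31178 (FBtr0084138) had no ratio on either array.

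**Figure D2:**
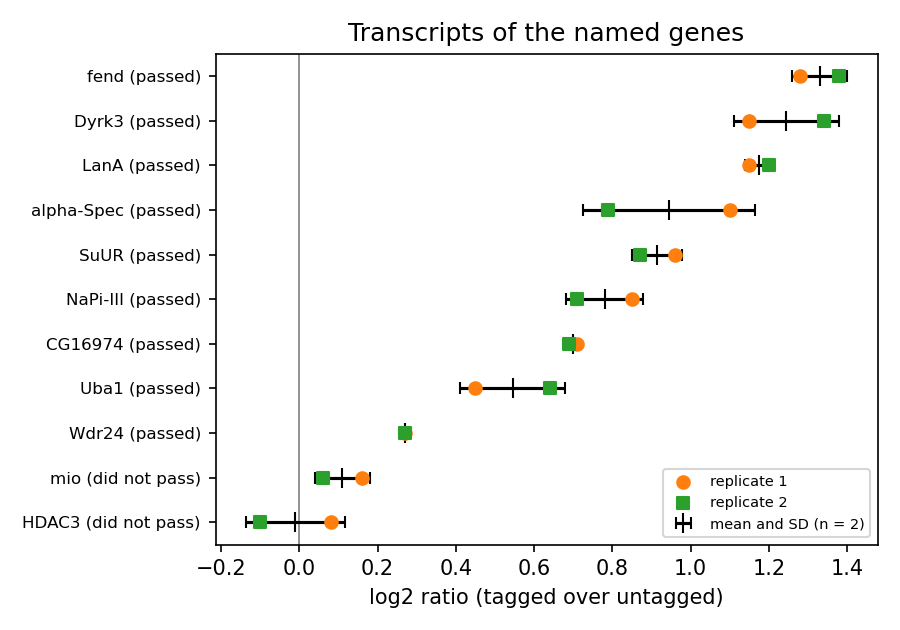
Log2 ratios (x axis, tagged over untagged RNA) of the 11 transcripts with 1 gene name (y axis), with circles for replicate 1, squares for replicate 2, and a bar for the mean with its SD (n = 2). The mean ratios run from -0.01 for HDAC3 to 1.33 for fend, and the transcripts of HDAC3 and mio did not pass the limma test.

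The 18 measured IDs that the gene table lists for 2 genes each were mostly lower in tagged RNA. Of these, 12 were lower, 1 was higher and 5 did not pass the limma test. Their median log2 ratio was -0.53, with quartiles of -1.02 and -0.06, and 13 of the 18 were below 0 on both arrays. Of all 8140 transcripts, 2760 were lower and 3400 higher. The set of 2-gene IDs was noticed because of its ratios, and a chance draw of 18 transcripts stays open.

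At the ends of the distribution stood transcripts without a gene name in the sources used here. The highest were FBtr0075173 at 2.25 ± 0.11 and FBtr0100246 at 2.12 ± 0.21 (SD, n = 2 each), which correspond to 4.76-fold and 4.35-fold higher levels in tagged RNA. The lowest were FBtr0075024 at -3.90 ± 0.04 and FBtr0112478 at -3.68 ± 0.08 (SD, n = 2 each), which correspond to 14.9-fold and 12.8-fold higher levels in untagged RNA. All 4 had a limma adjusted p of 0.0050. This was the lowest value that the adjustment gave, and many transcripts shared it, fend and LanA among them. Markers of glia, neurons, neuroblasts and other tissues fixed for this comparison were not analysed here, because their transcript IDs could not be paired with names from the table used.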

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

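The number of transcripts that differed between tagged and untagged RNA, 6160, stayed within 1.5 times under centring (6110), scaling to one spread (6256), robust eBayes (6346), leaving out exact zeros (6139), a threshold of 0.10 (6732) and, added after the data were examined, rounding error put back (6425), with 6153 calls shared. A threshold of 0.01 gave 3803 calls, 2030 higher and 1773 lower. Adding a 2-fold minimum gave 1838 calls, 859 higher and 979 lower. An ordinary one-sample t statistic without limma's moderation gave 0 calls in all, 0 higher and 0 lower, with 2763 at an unadjusted p under 0.05 among 7953 transcripts with unequal arrays. The calls thus rest on sharing the variance across transcripts. Turning the sign of array 2 gave 0 calls in limma, and 0 at an unadjusted p under 0.05. The closeness of the 2 arrays fixed that outcome in advance, so it is not a control for the calls. Fitted alone, the 11 named IDs gave 9 calls, 9 higher and 0 lower. The counts at least 2-fold apart on both arrays, 623 higher and 864 lower, became 1929 and 1702 at 1.5-fold, 46 and 334 at 3-fold, and 1525 and 1416 with values read as natural logs, a reading added after the data were examined. On 1 array alone, without a test, 802 to 996 were higher (996 without replicate 1) and 925 to 1073 lower. Among the 4750 transcripts at least 1.5-fold apart on either array, Pearson's r was 0.968, Spearman's rho 0.930, the SD of the difference 0.29 and the share of equal signs 99.3%. Of the 15 named transcripts and IDs, Wdr24 alone lost its call under centring (0.17). Leaving out a replicate left no residual degree of freedom, so the limma counts have no such value. The list tests and the alternatives for combining probes were not run, since no list had 5 named members and no gene had 2 named IDs. Without intensities, the signal over background behind a ratio is unknown.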

Other observations

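All tests in this part were chosen after the ratios had been seen. They concern 2 sets of transcript IDs that were noticed because of their ratios, so what follows are hypotheses, and a test of whether each set stands apart by chance would only restate what was noticed.

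The 18 IDs listed for 2 genes had a median log2 ratio of -0.53, against 0.12 for the other 8122 transcripts. An error confined to 1 array is argued against, because the difference was -0.60 on the array where it was smaller and -0.67 on the other. The closeness of the 2 arrays across all transcripts already made this likely, and an error shared by both was not tested. The style of the gene table's entries could be checked only on 5 IDs of 1 gene found through the same kind of longer synonym. Their median was 0.66 above that of all transcripts, the other way from the 2-gene IDs. While 5 of 5 lay above the median of the 2-gene IDs, that median is close to the lower quartile of all transcripts (-0.54), which most transcripts exceed. So few IDs cannot decide whether the style of entry plays a part. A short RNA offers fewer uridines for thiol tagging, so a length effect of the purification is a candidate explanation. The lengths of these transcripts were not used, so a length effect was not tested here. A chance draw of 18 transcripts, a lower level of these transcripts in glia than in other cells, and a smaller newly made share of them stay open as well.

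IDs that begin with FBtr01 had a median log2 ratio of 0.49 (817 transcripts), against 0.08 for IDs that begin with FBtr00 (7323 transcripts). The difference was 0.41, with a bootstrap 95% interval of 0.36 to 0.48. That interval resampled single transcripts as if they were independent, so it does not measure error between arrays. An error confined to 1 array is argued against by a difference of at least 0.40 on each array. The closeness of the 2 arrays across all transcripts already made this likely, so the check adds little. An error shared by both arrays was not tested. With each run of consecutive numbers as 1 value (544 runs against 4099) the difference was 0.37 (bootstrap 95% interval 0.32 to 0.47). Most of the difference thus remained when unbroken runs counted once. Runs followed ID numbers and not genes, and an ID without both ratios broke a run. Repeated counting of transcripts of the same gene therefore stays open. Fewer FBtr01 IDs were measured on both arrays (40.2% against 54.5%), and weak signal near the filter stays open. The median of FBtr00 IDs measured on 1 array was 0.36 units below that of FBtr00 IDs measured on both (difference -0.36, bootstrap 95% interval -0.56 to -0.17), whereas in FBtr01 IDs this difference was 0.06 (-0.35 to 0.27), and no source says that empty cells mark weak signals. Transcript length, probe position and gene class stay open, and no biological explanation was tested.

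The 457 IDs with a ratio on 1 array spread more widely than the rest, with an SD of 1.18 against 0.88 for the values of IDs measured on both. Of these, 56 were at least 2-fold higher and 137 at least 2-fold lower in tagged RNA, without a replicate. Pairs of consecutive ID numbers had a correlation of 0.25 between their mean ratios (3497 pairs), and 0 pairs had identical values on both arrays. Their differences between arrays correlated at 0.12. The transcripts in the counts are therefore not independent of each other.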
